A study of Mus musculus with 27 samples.

How the data were processed

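The samples were mouse gastric organoids, with 21 libraries in 7 groups of 3, taken from the labels. The groups were Mist1- at passage 5, Mist1+ without a knockout label (called wild type) at passages 5, 10 and 15, and Gpx4 knockout at passages 5, 10 and 15. Another 6 of 27 libraries, sorted cells in 2 diet groups, have no columns in the table, so the planned diet comparison was not run.

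The deposited table gives raw read counts (counts) for 56691 genes in each library, as the authors counted them, and the fragments per kilobase of exon and 1e6 counts (FPKM) computed by the authors. The FPKM equalled the count divided by exonic length and library total in 100% of values, within 0.006. Per the submitters' processing notes, reads were trimmed with cutadapt 1.9.1, aligned with HISAT2 2.2.1 and counted with HTSeq 0.6.1 on GRCm38.p5. The strand setting is not stated, so counts of overlapping antisense genes are uncertain. Of 52073 gene identifiers shared with GENCODE M21, which is on GRCm38, 1472 had identical coordinates in the table, and 50383 of the 52071 on the same chromosome had the same span. The table's coordinates are thus on another build than the one named. In GENCODE M21, Gpx4 (ENSMUSG00000075706) is on chromosome 10 at 80047166 to 80056439. Bhlha15 (ENSMUSG00000052271) is on chromosome 5 at 144190286 to 144194441, and Pitx1 (ENSMUSG00000021506) on chromosome 13 at 55825051 to 55836192.

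The plan written before the data were examined set limma on log2(FPKM + 1), with edgeR on counts if the table held raw counts, which it did. Counts were fitted in edgeR 4.0.16 (R 4.3.3) with a group-means design over all 21 libraries. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15. That left 15115 genes with 99.91% of counts. Libraries were scaled by TMM, and differences were tested by the quasi-likelihood F-test with robust moderation. Adjusted p is by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The SE is the log2 fold change divided by the square root of F. The common dispersion was 0.00669, a biological coefficient of variation of 8.18%. Intervals are 95% counting intervals.

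There were 9 comparisons, Mist1+ against Mist1- at passage 5, knockout against wild type at each passage, passages 10 and 15 against 5 in each genotype, and the interaction of genotype with passage 15 against 5. Before the data were examined, 34 gene lists with 467 entries were fixed. These cover gastric and other cell types, ferroptosis, NRF2, glutathione, selenoproteins, stress, metabolism, signalling and inflammation. Of these, 26 had at least 5 tested genes and were tested in each comparison by camera with a preset correlation of 0.01, and 8 had fewer. Camera adjusted p is over the lists of a comparison. Camera with an estimated correlation and fry (limma 3.58.1) were alternatives.

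Named genes followed a rule set beforehand. Gpx4 and Bhlha15 are given throughout. Each comparison gives the 6 highest and 6 lowest called protein-coding genes with a symbol and non-overlapping libraries, without Gm-numbered or Rik models. From the lists it gives up to 4 members by smallest adjusted p. To limit length, after the data were seen, 1 or 2 of these members are printed for most lists, those with the smallest adjusted p, with the next that moved the other way where 2 agree.

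Alternatives were median ratio and quantile scaling, no low-count filter, a mean FPKM of at least 1, limma with a pseudocount of 1 or 0.1, only the groups compared, the replicate number as a block, robust moderation off, a 2-fold threshold, DESeq2 1.42.0 and each replicate left out. After seeing the data, limma as first planned, fits without wild-type passage 15 or with only its replicate 2, length and GC offsets, and library totals alone were added. A GC value was known for 91.85% of genes.

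The code was tested on simulated data of this depth and group size, with 66 or 67 genes changed per fold. It recovered 40.3% to 67.2% of 1.5-fold, 59.7% to 86.6% of 2-fold and 80.3% to 93.9% of 4-fold changes over the 9 comparisons. The share of calls that were false was 1.88% to 9.80%.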

Results

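RNA was sequenced from mouse stomach organoids in 7 groups of 3 libraries. Organoids labelled Mist1+ were sampled at passages 5, 10 and 15, with a Gpx4 knockout label or without (wild type). Those labelled Mist1- were sampled at passage 5. Mist1, encoded by Bhlha15, is a transcription factor of secretory cells such as gastric chief cells. Gpx4 is the selenoenzyme that reduces lipid hydroperoxides and restrains ferroptosis. The 21 libraries held 13805585 to 19608956 counts in genes, and 15115 genes were tested. Levels are counts per 1e6 of the TMM-scaled library total (CPM), as mean ± SD (n = 3), and log2 fold changes carry their SE.

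Rose and fell mean an adjusted p under 0.05, and other genes of a list were not called. Counts adjusted over the list alone are given where they differ. Beside a list stand its median log2 fold change, again with genes at 0 counts at their bound where that differs, and camera's adjusted p. Each comparison gives 10 fixed lists and up to 8 with the smallest camera p. Of 234 list tests in all, 108 had an adjusted p under 0.05. The adjusted p with an estimated correlation follows, as estimated, where it ended the call. The labels do not say whether the 3 libraries of a group are separate cultures, so p-values measure the spread between libraries only. That spread was fitted for each gene over all 21 libraries, so groups outside a comparison also enter its p-values. In 6 groups the spread between replicates exceeded counting noise, with a chi-square per degree of freedom of 1.57 to 2.64 in 18 pairs. In wild-type passage 15 the 3 pairs gave 17.2 to 79.8. The biological coefficient of variation was 21.01% there, against 1.88% to 3.09% in the other groups. A group at 0 counts gives a bound against a floor of 3 counts over the group, and 1 to 3 counts give a ratio with its 95% counting interval. Both cover counting error only. The highest and lowest genes are 6 protein-coding called genes at each end whose libraries did not overlap.

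**Figure D1:**
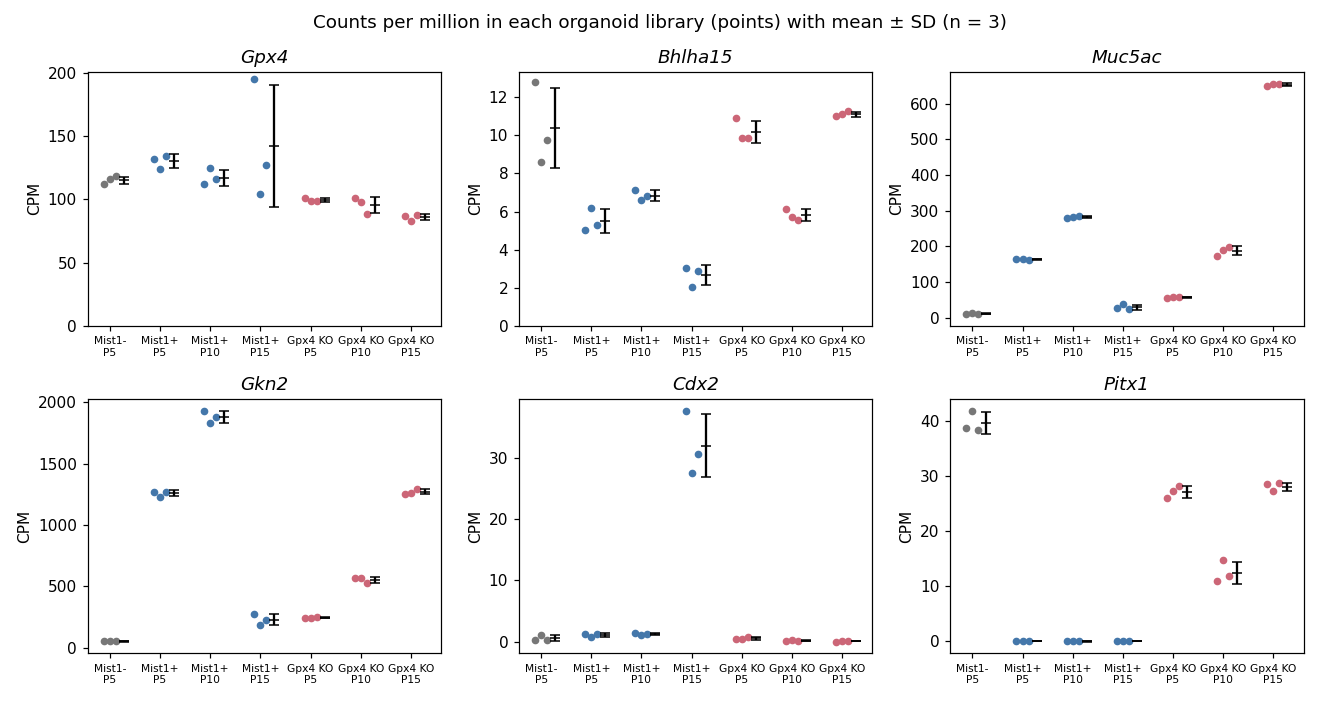
CPM (y axis) of 6 genes in each organoid library (points) with mean ± SD (n = 3) for 7 groups (x axis). Gpx4 was 130 CPM in wild-type and 99.5 CPM in knockout organoids at passage 5, and Muc5ac ranged from 11 CPM in Mist1- to 654 CPM in knockout passage 15 organoids.

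Mist1+ organoids at passage 5 carried more of the transcripts of surface mucous (pit) cells than Mist1- organoids. The gastrokines rose, with Gkn1 (933 ± 24 against 30.5 ± 0.46 CPM, log2 4.94 ± 0.15, adjusted p = 3.34e-16) and Gkn2 (1260 ± 25 against 55 ± 3.3 CPM, log2 4.51 ± 0.1, adjusted p = 4.46e-18), as did the surface antigen Psca (248 ± 6 against 14 ± 1.8 CPM, log2 4.14) and cathepsin E, Ctse (371 ± 6.1 against 74.5 ± 3.9 CPM, log2 2.32). Of 8 pit cell genes tested, 8 rose and 0 fell (median 3.11, adjusted p = 6.97e-53). Bhlha15 itself fell in Mist1+ organoids (5.5 ± 0.63 against 10.4 ± 2.1 CPM, log2 -0.91 ± 0.14, adjusted p = 1.89e-05). Gpx4 did not pass the test (130 ± 5.6 against 115 ± 2.9 CPM, log2 0.17, adjusted p = 0.353), although it did without wild-type passage 15 in the fit (adjusted p = 3.42e-05). The hedgehog ligand Shh (4.28 ± 0.54 CPM against 0 counts, at least 73.4-fold) was among the highest genes, with Rhox5 (3.09 ± 1.1 CPM against 0 counts, at least 52.8-fold), the natriuretic peptide receptor Npr3 (2.67 ± 0.63 CPM against 0 counts, at least 45.7-fold), Adcy2 (2 ± 0.32 CPM against 0 counts, at least 34.3-fold), Galnt5 (1.86 ± 0.58 CPM against 0 counts, at least 31.9-fold) and Srpx2 (1.68 ± 0.46 CPM against 0 counts, at least 28.8-fold). The lowest were the homeobox gene Pitx1 (0.0692 ± 0.069 against 39.7 ± 2 CPM, ratio 576, interval 197 to 2790, 3 counts), Nrn1 (log2 -7.2 ± 0.36), Gpc6 (0 counts against 0.819 ± 0.23 CPM, at least 11.8-fold), Bend5 (0 counts against 0.664 ± 0.22 CPM, at least 9.58-fold), Ppp1r3a (log2 -6.04 ± 0.39) and the collagen Col27a1 (0 counts against 0.411 ± 0.36 CPM, at least 5.92-fold). Adjusted p of these genes was at most 0.00487.

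Other gastric cell types did not move as 1 group, and SPEM stands for spasmolytic polypeptide-expressing metaplasia. Of 4 chief cell genes, 2 rose and 1 fell (median 0.1). The filter left out Gif, Pga5, Lipf and Chia1 of this list, and among others Atp4b (parietal) and Krt5, Krt14 and Trp63 (squamous). Pgc (log2 3.91 ± 0.14) and Rab3d (log2 0.21 ± 0.053) rose, and Xbp1 (log2 0 ± 0.048, adjusted p = 0.993) did not pass. Of 9 mucous neck and SPEM genes, 5 rose and 2 fell (median 0.28, adjusted p = 4.43e-07). Gkn3 (log2 4.84 ± 0.091) and the transcription factor Sox9 (log2 2.39 ± 0.056) rose, and the trefoil factor Tff2 (log2 -4.27 ± 0.18) fell. Of 6 parietal cell genes, 2 rose and 2 fell (median -0.28, mean -0.32 but camera upward, adjusted p = 0.203). The sodium-proton exchanger Slc9a4 (log2 2.16 ± 0.069) rose, and Clic6 (log2 -2.56 ± 0.23) fell. Of 10 stem and isthmus genes, 1 rose and 5 fell (median -0.17, adjusted p = 0.298). The Wnt feedback gene Axin2 (log2 1.84 ± 0.14) rose, and the stem cell receptor Lgr5 (log2 -1.66 ± 0.13) fell. Of 8 intestinal genes, 3 rose and 2 fell (median 1.17, adjusted p = 0.000204). Villin, Vil1, (log2 1.34 ± 0.042) and Olfm4 (log2 3.29 ± 0.11) rose, and Muc2 (log2 -2.02 ± 0.44) fell.

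Of 17 ferroptosis defence genes, 8 rose and 2 fell (9 rose and 2 fell over the list alone, median 0.17, adjusted p = 0.095). The membrane acyltransferase Mboat2 (log2 1.8 ± 0.12) and Mboat1 (log2 0.48 ± 0.041) rose, and the cystine transporter chain Slc3a2 (log2 -0.57 ± 0.073) fell. Of 14 ferroptosis drivers and markers, 5 rose and 3 fell (median -0.05, mean 0.13 but camera downward, adjusted p = 0.668). The glutathione-degrading Chac1 (log2 -2.2 ± 0.13) fell, and the polyamine-degrading Sat1 (log2 0.86 ± 0.054) rose. Of 22 NRF2 targets, 10 rose and 3 fell (12 rose and 3 fell over the list alone, median 0.2, adjusted p = 0.00247, estimated 0.0562). Me1 (log2 1.17 ± 0.048) and Ugdh (log2 0.97 ± 0.043) rose, and Gstm1 (log2 -0.75 ± 0.091) fell. NRF2 is a transcription factor of antioxidant genes.

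Of 16 hypoxia and glycolysis genes, 1 rose and 15 fell (median -0.73, adjusted p = 1.86e-18). Ndrg1 (log2 -1.76 ± 0.055) fell. Of 15 integrated stress response genes, 2 rose and 13 fell (median -0.8, adjusted p = 2.54e-11). Atf3 (log2 -1.19 ± 0.06) fell. Of 17 p53 targets, 13 rose and 0 fell (median 0.66, adjusted p = 1.32e-06). Ccng1 (log2 0.78 ± 0.053) rose. Of 13 fatty acid oxidation and PPAR targets, 10 rose and 1 fell (median 0.4, adjusted p = 2.17e-06). Angptl4 (log2 2.83 ± 0.12) rose. Other lists past the threshold were proliferation genes (0 rose and 12 fell of 20, median -0.2, adjusted p = 0.0145), YAP targets and regenerative genes (8 rose and 3 fell of 13, median 0.39, adjusted p = 0.0105, estimated 0.194), interferon response genes (7 rose and 0 fell of 10, median 0.82, adjusted p = 0.0171) and unfolded protein response genes (0 rose and 6 fell of 14, median -0.1, adjusted p = 0.0467, estimated 0.105). In Mist1+ against Mist1- organoids at passage 5 the interferon list had an adjusted p of 0.0846 without wild-type passage 15 in the fit.

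For selenoproteins 6 rose, 0 fell and 13 were not called (median 0.1, adjusted p = 0.186), for glutathione metabolism 12 rose, 3 fell and 5 were not called (12 rose and 4 fell over the list alone, median 0.38, adjusted p = 0.0979), and for Wnt targets 7 rose, 2 fell and 1 was not called (median 0.66, adjusted p = 0.116). For NF-kB genes 6 rose, 2 fell and 6 were not called (6 rose and 3 fell over the list alone, median 0.17, adjusted p = 0.19), for antigen presentation 4 rose, 2 fell and 3 were not called (median 0.2, mean 0.19 but camera downward, adjusted p = 0.982), and for immediate early and heat shock genes 4 rose, 5 fell and 4 were not called (5 rose and 5 fell over the list alone, median -0.04, adjusted p = 0.095). For cholesterol synthesis 9 rose, 2 fell and 5 were not called (median 0.21, adjusted p = 0.203), and for fatty acid synthesis 1 rose, 5 fell and 5 were not called (median -0.16, adjusted p = 0.0805). For nuclear-encoded OXPHOS 0 rose, 1 fell and 18 were not called (0 rose and 0 fell over the list alone, median 0, mean 0.01 but camera downward, adjusted p = 0.766), and for mitochondrially encoded mRNAs 3 rose, 1 fell and 7 were not called (4 rose and 1 fell over the list alone, median 0.21, adjusted p = 0.101). Lists with fewer than 5 tested genes had no list test. These were the enteroendocrine (1 rose and 0 fell), tuft (1 rose, 0 fell and 3 were not called), squamous (1 rose, 1 fell and 2 were not called) and fibroblast (0 rose, 0 fell and 1 was not called) lists. The others were the immune (0 rose, 1 fell and 2 were not called), endothelial (0 rose and 1 fell) and epithelial-mesenchymal transition (1 rose, 1 fell and 2 were not called) lists and the chief cell list.

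In this comparison 5290 genes were called by edgeR's quasi-likelihood test, 2842 higher and 2448 lower in Mist1+ organoids, and 1337 differed by 2-fold or more.

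Gpx4 counts in the organoids labelled Gpx4 knockout were lower, but not absent, in each library. They were 101, 98.9 and 98.2 CPM at passage 5, 101, 97.5 and 88.1 CPM at passage 10, and 86.8, 83.1 and 87.8 CPM at passage 15. Wild-type Mist1+ libraries held 132, 124 and 134 CPM of Gpx4 at passage 5, 112, 125 and 116 CPM at passage 10, and 195, 104 and 127 CPM at passage 15. Mist1- libraries held 112, 116 and 118 CPM of Gpx4. Counts per gene cannot show which exons were read, so a transcript that lacks deleted exons would still be counted.

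Knockout organoids at passage 5 had lower pit cell and higher proliferation transcripts than wild-type Mist1+ organoids. Among 8 pit cell genes, 0 rose and 8 fell (median -1.51, adjusted p = 1.42e-34), such as Gkn2 (247 ± 7.7 against 1260 ± 25 CPM, log2 -2.35 ± 0.094, adjusted p = 6.98e-14), Psca (48 ± 0.88 against 248 ± 6 CPM, log2 -2.37), Ctse (131 ± 1.9 against 371 ± 6.1 CPM, log2 -1.51) and the mucin-like Mucl3 (119 ± 4.4 against 265 ± 2.5 CPM, log2 -1.16). Gpx4 fell (99.5 ± 1.7 against 130 ± 5.6 CPM, log2 -0.38 ± 0.14, adjusted p = 0.0362). The call held without wild-type passage 15 in the fit, but not in the 6 fits without 1 library compared (adjusted p = 0.0524 to 0.101). Bhlha15 rose (10.2 ± 0.58 against 5.5 ± 0.63 CPM, log2 0.89 ± 0.14, adjusted p = 3.74e-05). The highest genes were the transporter Slc22a29 (13 ± 0.089 CPM against 0 counts, at least 188-fold), Pitx1 (27.2 ± 1.1 against 0.0692 ± 0.069 CPM, ratio 394, interval 135 to 1910, 3 counts), the anion exchanger Slc26a4 (0.775 ± 0.15 CPM against 0 counts, at least 11.3-fold), Col27a1 (0.337 ± 0.066 CPM against 0 counts, at least 4.86-fold), podoplanin, Pdpn (log2 5.28 ± 0.4), and Zfp345 (0.267 ± 0.19 CPM against 0 counts, at least 3.78-fold). The lowest were the transcription factor Tfap2a (0 counts against 5.88 ± 1.2 CPM, at least 105-fold), Capn11 (0 counts against 4.34 ± 0.46 CPM, at least 77.8-fold), Ccnb1ip1 (0 counts against 2.85 ± 0.16 CPM, at least 51-fold), Gbp2b (0 counts against 2.31 ± 0.76 CPM, at least 41.6-fold), Xlr3a (0 counts against 2.05 ± 0.59 CPM, at least 36.6-fold) and the uroplakin Upk1b (0 counts against 0.594 ± 0.33 CPM, at least 10.7-fold). Slc22a29, Gbp2b and Xlr3a have near-identical copies, so their counts are uncertain. Adjusted p of the other genes was at most 0.0362.

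Among 20 proliferation genes, 20 rose and 0 fell (median 0.46, adjusted p = 5.99e-11). Cyclin A2, Ccna2, (log2 0.56 ± 0.048) and Rrm2 (log2 0.54 ± 0.053) rose. Among 4 chief cell genes, 2 rose and 1 fell (2 rose and 2 fell over the list alone, median 0.19). Pgc (log2 -1.69 ± 0.11) fell, and Xbp1 (log2 0.5 ± 0.048) rose, and Rab3d (log2 -0.12 ± 0.053, adjusted p = 0.108) did not pass. Among 9 mucous neck and SPEM genes, 3 rose and 4 fell (4 rose and 4 fell over the list alone, median 0.04, mean -0.03 but camera downward, adjusted p = 0.107). Sox9 (log2 -1.7 ± 0.054) and Gkn3 (log2 -1.48 ± 0.075) fell, and Tff2 (log2 1.95 ± 0.17) rose. Among 6 parietal cell genes, 2 rose and 2 fell (median 0.06, mean 0.04 but camera downward, adjusted p = 0.107). Slc9a4 (log2 -1.38 ± 0.067) and the potassium channel Kcnq1 (log2 -0.77 ± 0.072) fell, and the proton pump subunit Atp4a (log2 1.15 ± 0.25) rose. Among 10 stem and isthmus genes, 5 rose and 2 fell (median 0.2, adjusted p = 0.107). Lgr5 (log2 1.21 ± 0.13) rose, and Axin2 (log2 -1.01 ± 0.13) fell. Also counted were intestinal genes (2 rose and 2 fell of 8, 3 rose and 4 fell over the list alone, median 0.16, adjusted p = 0.00611) and squamous genes (0 rose and 2 fell of 4, median -0.45).

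Among 22 NRF2 targets, 1 rose and 15 fell (2 rose and 17 fell over the list alone, median -0.39, adjusted p = 2.16e-08). Ugdh (log2 -0.93 ± 0.043) and the quinone reductase Nqo1 (log2 -1.55 ± 0.096) fell. Among 17 ferroptosis defence genes, 1 rose and 7 fell (1 rose and 10 fell over the list alone, median -0.33, adjusted p = 0.0228, estimated 0.146). Nfe2l2, which encodes NRF2, (log2 -0.51 ± 0.041) and the glutathione synthesis gene Gclm (log2 -0.54 ± 0.046) fell. Among 14 ferroptosis drivers and markers, 3 rose and 5 fell (median -0.06, adjusted p = 0.447). Sat1 (log2 -0.55 ± 0.054) and heme oxygenase 1, Hmox1, (log2 -0.54 ± 0.064) fell, and the prostaglandin synthase Ptgs2 (log2 1.03 ± 0.17) rose. Among 20 glutathione metabolism genes, 2 rose and 13 fell (3 rose and 14 fell over the list alone, median -0.46, adjusted p = 0.000655, estimated 0.189). Gsto1 (log2 -0.92 ± 0.076) fell.

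Among 17 p53 targets, 1 rose and 14 fell (median -0.51, adjusted p = 2.16e-08). Ccng1 (log2 -0.66 ± 0.053) fell. Among 14 unfolded protein response genes, 11 rose and 0 fell (median 0.32, adjusted p = 1.56e-05). Among 13 fatty acid oxidation and PPAR targets, 0 rose and 9 fell (median -0.32, adjusted p = 0.000592). Plin2 (log2 -1.01 ± 0.09) fell. Among 13 YAP targets and regenerative genes, 5 rose and 8 fell (median -0.5, adjusted p = 0.00095, estimated 0.115). The alarmin Il33 (log2 -1.4 ± 0.051) fell. Among 14 NF-kB and inflammatory genes, 5 rose and 2 fell (7 rose and 3 fell over the list alone, median 0.13, adjusted p = 0.00095, estimated 0.0517).

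At passage 5, 4547 genes were called, 1970 higher and 2577 lower in the knockout organoids, and 1004 by 2-fold or more. This comparison shares the wild-type passage 5 libraries with that of Mist1+ and Mist1- organoids. With only the groups compared in the fit 7035 genes were called, and 7095 without wild-type passage 15.

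At passage 10 the knockout organoids again had lower pit cell and higher proliferation transcripts. Gpx4 did not pass the test (95.4 ± 6.5 against 117 ± 6.4 CPM, log2 -0.3, adjusted p = 0.094), although it did without wild-type passage 15 in the fit (adjusted p = 4.52e-12). Of 8 pit cell genes, 0 rose and 8 fell (median -1.35, adjusted p = 2.37e-26), with Mucl3 (91.7 ± 5.4 against 327 ± 1.3 CPM, log2 -1.83 ± 0.052, adjusted p = 2.86e-16), Gkn1 (349 ± 17 against 1370 ± 30 CPM, log2 -1.97), Gkn2 (553 ± 23 against 1880 ± 50 CPM, log2 -1.77) and Ctse (156 ± 3.2 against 329 ± 11 CPM, log2 -1.07). Bhlha15 did not pass (5.8 ± 0.32 against 6.84 ± 0.27 CPM, log2 -0.24, adjusted p = 0.206). Highest were the kinase Hunk (9.95 ± 0.25 CPM against 0 counts, at least 169-fold), Slc22a29 (5.09 ± 0.91 CPM against 0 counts, at least 87.7-fold), Pitx1 (12.5 ± 2 against 0.02 ± 0.035 CPM, ratio 631, interval 113 to 24900, 1 count), Armcx4 (2.03 ± 0.49 CPM against 0 counts, at least 34.8-fold), Smim10l2a (1.37 ± 0.7 CPM against 0 counts, at least 22.7-fold) and Palmd (1.28 ± 0.45 CPM against 0 counts, at least 22.4-fold). The lowest were Ccnb1ip1 (0 counts against 2.47 ± 0.32 CPM, at least 39.4-fold), Gbp2b (0 counts against 2.33 ± 0.73 CPM, at least 37.6-fold), coagulation factor V, F5 (0.0665 ± 0.064 against 5.81 ± 0.41 CPM, ratio 92.3, interval 31.3 to 450, 3 counts), Pcdh15 (0 counts against 0.499 ± 0.36 CPM, at least 8.14-fold), Tfap2a (log2 -6.00 ± 0.46) and Capn11 (0.0657 ± 0.072 against 3.44 ± 0.65 CPM, ratio 54.1, interval 18.2 to 265, 3 counts). Adjusted p of the called genes was at most 0.00182.

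Out of 20 proliferation genes, 20 rose and 0 fell (median 0.48, adjusted p = 3.11e-13). Cyclin B1, Ccnb1, (log2 0.74 ± 0.057) and Ccna2 (log2 0.59 ± 0.048) rose. Out of 4 chief cell genes, 1 rose and 2 fell (median -0.31). Rab3d (log2 -0.55 ± 0.053) fell, and Xbp1 (log2 0.25 ± 0.048) rose, and Pgc (log2 -0.38 ± 0.11) fell. Out of 9 mucous neck and SPEM genes, 3 rose and 5 fell (median -0.49, adjusted p = 0.0386, estimated 0.0962). Sox9 (log2 -1.38 ± 0.054) fell, and the water channel Aqp5 (log2 2.84 ± 0.15) rose. Out of 6 parietal cell genes, 0 rose and 2 fell (median -0.54, adjusted p = 0.0413, estimated 0.0905). Slc9a4 (log2 -0.93 ± 0.066) and Kcnq1 (log2 -0.56 ± 0.073) fell. Out of 10 stem and isthmus genes, 7 rose and 0 fell (median 0.28, adjusted p = 0.000423). Lgr5 (log2 1.75 ± 0.13) and Tnfrsf19 (log2 1.76 ± 0.19) rose. Also counted were intestinal genes (2 rose and 3 fell of 8, median -0.65, adjusted p = 0.976) and squamous genes (0 rose and 1 fell of 4, median 0.21).

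Out of 22 NRF2 targets, 0 rose and 11 fell (0 rose and 12 fell over the list alone, median -0.15, adjusted p = 0.000523). Ugdh (log2 -0.68 ± 0.042) and Nqo1 (log2 -1.24 ± 0.094) fell. Out of 17 ferroptosis defence genes, 2 rose and 4 fell (median 0, adjusted p = 0.976). Mboat2 (log2 1.34 ± 0.094) rose, and the glutathione synthesis gene Gclc (log2 -0.67 ± 0.077) fell. Out of 14 ferroptosis drivers and markers, 5 rose and 2 fell (median 0.08, adjusted p = 0.127). Ptgs2 (log2 1.5 ± 0.17) and the transferrin receptor Tfrc (log2 0.85 ± 0.1) rose, and Sat1 (log2 -0.38 ± 0.054) fell.

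Out of 17 p53 targets, 1 rose and 14 fell (1 rose and 15 fell over the list alone, median -0.58, adjusted p = 2.12e-07). Ccng1 (log2 -0.7 ± 0.053) fell. Out of 16 hypoxia and glycolysis genes, 12 rose and 1 fell (13 rose and 2 fell over the list alone, median 0.41, adjusted p = 2.71e-07). The mitophagy receptor Bnip3 (log2 0.92 ± 0.044) rose. Out of 13 fatty acid oxidation and PPAR targets, 0 rose and 6 fell (0 rose and 7 fell over the list alone, median -0.16, adjusted p = 0.000293). Ehhadh (log2 -2.05 ± 0.11) fell. Out of 11 mitochondrially encoded mRNAs, 0 rose and 10 fell (median -0.37, adjusted p = 0.000523, estimated 0.0633). mt-Cytb (log2 -0.57 ± 0.049), mt-Nd4 (log2 -0.53 ± 0.053), mt-Nd2 (log2 -0.34 ± 0.053) and mt-Co1 (log2 -0.33 ± 0.064) fell. With quantile normalised values mt-Nd2 turned to a log2 of 0.43.

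At passage 10, 5204 genes were called, 2408 higher and 2796 lower, and 1051 by 2-fold or more. Of 314 genes at 4-fold or more, 123 were so too between Mist1- and Mist1+ organoids at passage 5. In 118 of these the knockout organoids moved the way Mist1- organoids did. Across genes, which are not independent replicates, Pearson's r of these log2 fold changes was 0.49 and Spearman's rho was 0.49. Both changes subtract wild-type Mist1+ organoids and so are not independent, though no library is shared. The passage 5 and passage 10 comparisons shared 1311 genes called higher, against 314 by chance from their sizes, and 1762 called lower, against 477. Fits without 1 library of these groups lost the calls (adjusted p) of Pgc (1 of 6 fits, 0.0611 without knockout passage 10 replicate 3). Calls lost with quantile normalised values (adjusted p) were mt-Nd4 (0.844) and mt-Co1 (1).

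At passage 15 the pit cell genes went the opposite way, with higher levels in the knockout organoids. Gpx4 fell (85.9 ± 2.5 against 142 ± 48 CPM, log2 -0.72 ± 0.14, adjusted p = 0.000215), but was not called with only the groups compared in the fit (adjusted p = 0.0564). Its log2 fold change was -0.28 against wild-type replicate 2 alone and -0.43 without wild-type replicate 1. Of 8 pit cell genes, 6 rose and 1 fell (median 1.96, adjusted p = 4.6e-18), with the mucin Muc5ac (654 ± 3.1 against 28.7 ± 7.3 CPM, log2 4.51 ± 0.12, adjusted p = 2.74e-17), Mucl3 (149 ± 3 against 28.3 ± 1.6 CPM, log2 2.4), Gkn2 (1270 ± 19 against 230 ± 46 CPM, log2 2.46) and Gkn1 (780 ± 5.9 against 186 ± 58 CPM, log2 2.07). Bhlha15 rose (11.1 ± 0.11 against 2.66 ± 0.52 CPM, log2 2.08 ± 0.15, adjusted p = 5.33e-10). The highest genes were Pitx1 (28.1 ± 0.74 CPM against 0 counts, at least 442-fold), peroxidasin, Pxdn (19 ± 0.68 CPM against 0 counts, at least 298-fold), the homeobox genes Irx5 (13.2 ± 0.84 CPM against 0 counts, at least 208-fold) and Irx2 (5.98 ± 0.46 CPM against 0 counts, at least 94-fold), Slc22a29 (19.8 ± 3.4 against 0.024 ± 0.042 CPM, ratio 929, interval 166 to 36700, 1 count) and the claudin Cldn14 (3.11 ± 0.28 CPM against 0 counts, at least 48.8-fold). The lowest were necdin, Ndn (0 counts against 22.4 ± 4.3 CPM, at least 378-fold), Upk1b (0 counts against 14.7 ± 1.2 CPM, at least 250-fold), the intestinal factor Cdx2 (0.0385 ± 0.033 against 32 ± 5.2 CPM, ratio 809, interval 224 to 6690, 2 counts), Il5ra (log2 -9.35 ± 0.32), epiregulin, Ereg (0.0607 ± 0.11 against 39.4 ± 6.9 CPM, ratio 679, interval 232 to 3300, 3 counts), and the cadherin Cdh17 (0.0587 ± 0.0017 against 30.9 ± 5 CPM, ratio 532, interval 182 to 2580, 3 counts). Adjusted p of these genes was at most 0.000215.

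Of 4 chief cell genes, 4 rose and 0 fell (median 0.81). Rab3d (log2 0.88 ± 0.053), Xbp1 (log2 0.74 ± 0.048) and Pgc (log2 0.63 ± 0.12) rose. Of 9 mucous neck and SPEM genes, 5 rose and 3 fell (median 0.35, adjusted p = 0.00295). Dmbt1 (log2 4.56 ± 0.11) and Tff2 (log2 1.87 ± 0.17) rose, and Cftr (log2 -1.43 ± 0.16) fell. Of 6 parietal cell genes, 2 rose and 1 fell (median -0.12, mean 0.22 but camera upward, adjusted p = 0.742). Slc9a4 (log2 0.38 ± 0.066) and Clic6 (log2 2.29 ± 0.43) rose, and Kcnq1 (log2 -0.21 ± 0.073) fell. Of 10 stem and isthmus genes, 6 rose and 2 fell (median 0.27, adjusted p = 0.225). Runx1 (log2 0.66 ± 0.071) and Lgr5 (log2 0.95 ± 0.13) rose. Of 8 intestinal genes, 2 rose and 4 fell (2 rose and 5 fell over the list alone, median -1.4, adjusted p = 0.00875). Of 4 squamous genes, 0 rose and 4 fell (median -2.51).

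Of 22 NRF2 targets, 1 rose and 16 fell (1 rose and 17 fell over the list alone, median -0.33, adjusted p = 1.97e-05). Hmox1 (log2 -1.27 ± 0.066) and Gclm (log2 -0.76 ± 0.046) fell. Of 17 ferroptosis defence genes, 3 rose and 10 fell (3 rose and 11 fell over the list alone, median -0.22, adjusted p = 0.0485, estimated 0.254). Mboat2 (log2 1.94 ± 0.1) rose, and Nfe2l2 (log2 -0.69 ± 0.042) fell. Of 14 ferroptosis drivers and markers, 6 rose and 4 fell (median -0.01, mean -0.14 but camera upward, adjusted p = 0.949). Slc11a2 (log2 0.56 ± 0.063) rose.

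Of 13 YAP targets and regenerative genes, 2 rose and 10 fell (median -1.36, adjusted p = 2.18e-23). Amphiregulin, Areg, (log2 -3.5 ± 0.085) fell. Of 17 p53 targets, 0 rose and 16 fell (median -1.21, adjusted p = 2.18e-23). Plk2 (log2 -1.48 ± 0.045) fell. Of 16 hypoxia and glycolysis genes, 13 rose and 0 fell (median 0.64, adjusted p = 1.91e-15). Bnip3 (log2 2.00 ± 0.046) rose. Of 14 NF-kB and inflammatory genes, 11 rose and 1 fell (median 0.75, adjusted p = 8.47e-09). The chemokine Cxcl5 (log2 1.17 ± 0.057) rose. Of 14 unfolded protein response genes, 10 rose and 0 fell (10 rose and 1 fell over the list alone, median 0.36, adjusted p = 0.000279).

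At passage 15, 7396 genes were called, 3568 higher and 3828 lower, and 1627 by 2-fold or more. With only the groups compared in the fit the count was 2735. The wild-type replicates differed in the trend of their values on gene length, with slopes of -0.333, 0.031 and -0.13 log2 CPM per doubling of length. The other 18 libraries had slopes of 0.003 to 0.049. Called genes shared with passage 5 were 657 higher, against 465 for independent calls equally likely for each gene, and 943 lower, against 653. With passage 10 they were 534 higher, against 568, and 760 lower, against 708. In all 3 passages 355 genes were called higher and 606 lower. Fits without 1 library of these groups lost the calls (adjusted p) of Kcnq1 (2 of 6 fits, up to 0.171). Calls lost (adjusted p) were Slc9a4 with only the groups compared in the fit (0.0578) and Clic6 with quantile normalised values (0.579).

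**Figure D2:**
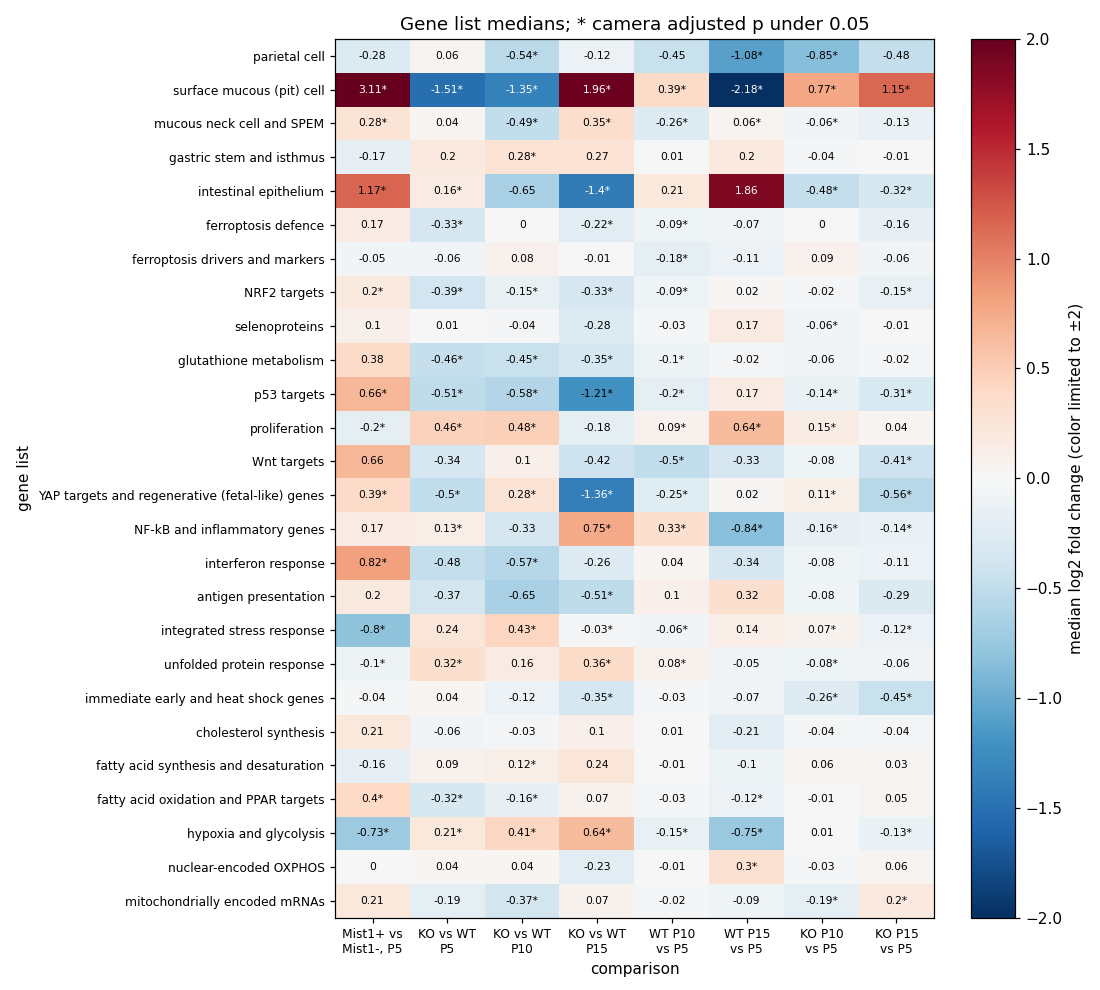
Median log2 fold change of each gene list (y axis) in 8 comparisons (x axis), with genes at 0 counts set to their bound; color shows the value, limited to 2 in either direction, and a star a camera adjusted p under 0.05. The pit cell median was 3.11 in Mist1+ against Mist1- organoids, and -1.51, -1.35 and 1.96 in knockout against wild type at passages 5, 10 and 15.

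**Figure D3:**
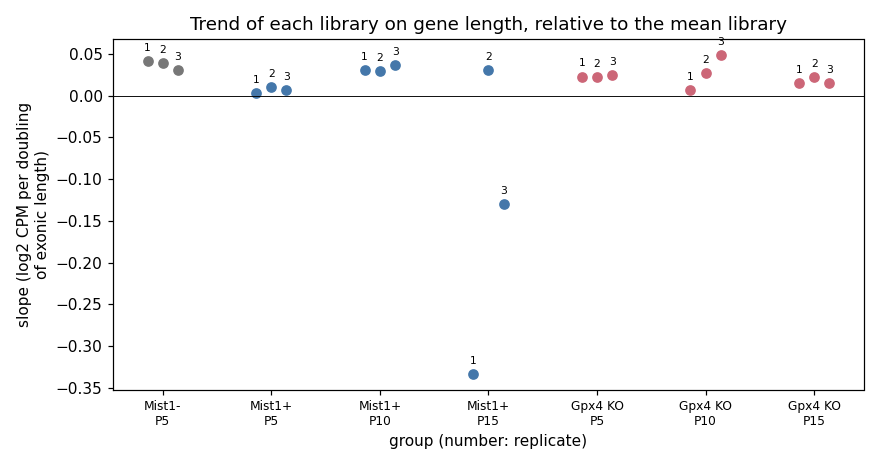
Slope of each library's log2 CPM per doubling of exonic gene length (y axis) for 7 groups (x axis), with 3 points per group, 1 per library. Wild-type passage 15 replicates 1 and 3 lie at -0.333 and -0.13, and the 18 libraries of the other groups at 0.003 to 0.049.

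In wild-type Mist1+ organoids passage 10 had higher levels of 4 pit cell genes than passage 5. Gpx4 did not pass (117 ± 6.4 against 130 ± 5.6 CPM, log2 -0.14, adjusted p = 0.734), although it did without wild-type passage 15 in the fit (-0.15, adjusted p = 0.00162). Bhlha15 did not pass (6.84 ± 0.27 against 5.5 ± 0.63 CPM, log2 0.32, adjusted p = 0.299). Among 8 pit cell genes, 4 rose and 1 fell (5 rose and 1 fell over the list alone, median 0.39, adjusted p = 9.2e-07), with Muc5ac (282 ± 2.9 against 164 ± 1 CPM, log2 0.78 ± 0.1, adjusted p = 3.29e-05), Gkn2 (1880 ± 50 against 1260 ± 25 CPM, log2 0.58), Gkn1 (1370 ± 30 against 933 ± 24 CPM, log2 0.55) and Mucl3 (327 ± 1.3 against 265 ± 2.5 CPM, log2 0.3). Highest were Ugt1a7c (1.21 ± 0.48 against 0.0699 ± 0.071 CPM, ratio 17.1, interval 5.57 to 85.1, 3 counts), Gbp5 (log2 2.77 ± 0.54), Hdgfl3 (log2 2.5 ± 0.42), the aquaglyceroporin Aqp9 (log2 2.31 ± 0.63), Tesc (log2 2.17 ± 0.39) and the mucin Muc16 (log2 2.07 ± 0.31). The lowest were Hunk (0 counts against 0.138 ± 0.12 CPM, at least 2.34-fold), Rhox5 (log2 -3.93 ± 0.45), Gimap1 (log2 -3.43 ± 0.58), Adcy1 (log2 -3.02 ± 0.66), Iqcg (log2 -2.42 ± 0.55) and Gdf10 (log2 -2.36 ± 0.6). Ugt1a7c shares exons with its gene family, so its count is uncertain. Called genes had an adjusted p up to 0.0478.

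Among 4 chief cell genes, 1 rose and 1 fell (median 0.11). Pgc (log2 -0.47 ± 0.1) fell, and Rab3d (log2 0.22 ± 0.053) rose, and Xbp1 (log2 0 ± 0.048, adjusted p = 0.997) did not pass. Among 9 mucous neck and SPEM genes, 0 rose and 2 fell (0 rose and 6 fell over the list alone, median -0.26, adjusted p = 8.55e-09). Gkn3 (log2 -0.77 ± 0.073) and Sox9 (log2 -0.38 ± 0.051) fell. Among 6 parietal cell genes, 1 rose and 1 fell (1 rose and 2 fell over the list alone, median -0.45, adjusted p = 0.0566). Kcnq1 (log2 -0.54 ± 0.072) fell, and Atp4a (log2 1.14 ± 0.26) rose. Among 10 stem and isthmus genes, 0 rose and 3 fell (1 rose and 3 fell over the list alone, median 0.01, mean -0.21 but camera downward, adjusted p = 0.0566). Axin2 (log2 -0.91 ± 0.13) and Lgr5 (log2 -0.68 ± 0.14) fell. Also counted were intestinal genes (2 rose and 1 fell of 8, 2 rose and 2 fell over the list alone, median 0.21, mean 0.11 but camera downward, adjusted p = 0.937) and squamous genes (0 rose and 1 fell of 4, median -0.35).

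Among 17 ferroptosis defence genes, 0 rose and 4 fell (0 rose and 5 fell over the list alone, median -0.09, adjusted p = 0.0011). Gclm (log2 -0.24 ± 0.046) and Nfe2l2 (log2 -0.22 ± 0.041) fell. Among 14 ferroptosis drivers and markers, 0 rose and 7 fell (median -0.18, adjusted p = 4.84e-05). Hmox1 (log2 -0.58 ± 0.064) and Sat1 (log2 -0.33 ± 0.054) fell. Among 22 NRF2 targets, 0 rose and 4 fell (1 rose and 7 fell over the list alone, median -0.09, adjusted p = 0.000299).

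Among 13 YAP targets and regenerative genes, 0 rose and 6 fell (1 rose and 8 fell over the list alone, median -0.25, adjusted p = 1.96e-21). Il33 (log2 -0.81 ± 0.05) fell. Among 14 NF-kB and inflammatory genes, 7 rose and 0 fell (11 rose and 0 fell over the list alone, median 0.33, adjusted p = 2.04e-10). Tnf (log2 0.38 ± 0.071) rose. Among 16 hypoxia and glycolysis genes, 0 rose and 5 fell (0 rose and 7 fell over the list alone, median -0.15, adjusted p = 4.43e-08). Egln3 (log2 -0.43 ± 0.052) fell. Among 17 p53 targets, 0 rose and 3 fell (0 rose and 4 fell over the list alone, median -0.2, adjusted p = 1.26e-06). Pmaip1 (log2 -0.38 ± 0.055) fell. Among 10 Wnt targets, 0 rose and 6 fell (0 rose and 9 fell over the list alone, median -0.5, adjusted p = 6.53e-09).

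Between these passages 738 genes were called, 309 higher and 429 lower at passage 10, and 113 by 2-fold or more. The count was 2827 with only the groups compared in the fit and 2766 without wild-type passage 15. Fits without 1 library of these groups lost the calls (adjusted p) of Aqp9 (5 of 6 fits, up to 0.165), Hunk (4 of 6 fits, up to 0.371), Iqcg (2 of 6 fits, up to 0.0705), Gdf10 (4 of 6 fits, up to 0.111), Pgc (1 of 6 fits, 0.0557 without wild-type passage 5 replicate 2), Rab3d (3 of 6 fits, up to 0.0885) and Atp4a (1 of 6 fits, 0.0626 without wild-type passage 5 replicate 3).

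Wild-type organoids at passage 15 carried less of the pit cell transcripts than at passage 5. Gpx4 was not called (142 ± 48 against 130 ± 5.6 CPM, log2 0.13, adjusted p = 0.441), but it was called lower without replicate 1 of passage 15 (log2 -0.16, adjusted p = 0.0353) and higher without replicate 2 (0.31, 0.0162). Its log2 fold change was -0.32 with only replicate 2, a lone library. Bhlha15 fell (2.66 ± 0.52 against 5.5 ± 0.63 CPM, log2 -1.06 ± 0.17, adjusted p = 2.87e-05). Pit cell genes numbered 8, of which 1 rose and 7 fell (median -2.18, adjusted p = 3.48e-25), with Mucl3 (28.3 ± 1.6 against 265 ± 2.5 CPM, log2 -3.23 ± 0.057, adjusted p = 7.47e-20), Muc5ac (28.7 ± 7.3 against 164 ± 1 CPM, log2 -2.51), Gkn2 (230 ± 46 against 1260 ± 25 CPM, log2 -2.45) and Ctse (120 ± 2.5 against 371 ± 6.1 CPM, log2 -1.63). The highest genes were the ligand Bmp3 (7.41 ± 0.36 CPM against 0 counts, at least 107-fold), Dmrt2 (2 ± 0.19 CPM against 0 counts, at least 29.2-fold), Ndn (log2 7.27 ± 0.36), Synpr (1.05 ± 0.22 CPM against 0 counts, at least 15.4-fold), Tex19.2 (0.872 ± 0.17 CPM against 0 counts, at least 12.6-fold) and Evc (7.7 ± 1.6 against 0.0699 ± 0.071 CPM, ratio 110, interval 37.4 to 537, 3 counts). The lowest were Zfp987 (0 counts against 9.08 ± 0.98 CPM, at least 143-fold), Irx5 (0 counts against 8.33 ± 0.96 CPM, at least 131-fold), Lipo3 (0.024 ± 0.042 against 15.7 ± 1.7 CPM, ratio 741, interval 133 to 29300, 1 count), the vitamin D hydroxylase Cyp2r1 (0 counts against 2.94 ± 0.56 CPM, at least 46.2-fold), Ccnb1ip1 (0 counts against 2.85 ± 0.16 CPM, at least 44.8-fold) and Lpar5 (0 counts against 2.38 ± 0.6 CPM, at least 37.5-fold). Zfp987 and Lipo3 have near-identical copies, so their counts are uncertain. Adjusted p of the called genes was at most 0.000735.

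Out of 20 proliferation genes, 19 rose and 0 fell (median 0.64, adjusted p = 1.15e-11). Mcm5 (log2 0.79 ± 0.048) and Ccna2 (log2 0.67 ± 0.048) rose. Out of 4 chief cell genes, 0 rose and 4 fell (median -0.89). Pgc (log2 -1.96 ± 0.12), Rab3d (log2 -0.73 ± 0.053) and Xbp1 (log2 -0.25 ± 0.048) fell. Out of 9 mucous neck and SPEM genes, 2 rose and 4 fell (median 0.06, mean -0.72 but camera downward, adjusted p = 3.68e-06). Dmbt1 (log2 -4.78 ± 0.11) and Gkn3 (log2 -2.49 ± 0.078) fell. Out of 6 parietal cell genes, 1 rose and 4 fell (median -1.08, adjusted p = 0.0425, estimated 0.101). Slc9a4 (log2 -1.47 ± 0.067) and Kcnq1 (log2 -0.7 ± 0.072) fell, and Atp4a (log2 2.01 ± 0.24) rose. Out of 10 stem and isthmus genes, 5 rose and 2 fell (median 0.2, adjusted p = 0.439). Tnfrsf19 (log2 1.63 ± 0.17) and Stmn1 (log2 0.79 ± 0.1) rose, and Axin2 (log2 -0.98 ± 0.13) fell. Out of 8 intestinal genes, 5 rose and 2 fell (median 1.86, adjusted p = 0.812). Out of 4 squamous genes, 3 rose and 0 fell (median 0.84).

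Out of 17 ferroptosis defence genes, 4 rose and 8 fell (median -0.07, adjusted p = 0.486). Gclc (log2 -0.74 ± 0.077) and Mboat1 (log2 -0.39 ± 0.041) fell. Out of 14 ferroptosis drivers and markers, 2 rose and 7 fell (median -0.11, adjusted p = 0.262). Sat1 (log2 -1.1 ± 0.055) and the ferritin receptor Ncoa4 (log2 -1.73 ± 0.15) fell, and Ptgs2 (log2 0.8 ± 0.18) rose. Out of 22 NRF2 targets, 7 rose and 9 fell (median 0.02, mean -0.13 but camera downward, adjusted p = 0.395). Ugdh (log2 -0.66 ± 0.042) and Me1 (log2 -0.6 ± 0.047) fell.

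Out of 16 hypoxia and glycolysis genes, 0 rose and 12 fell (0 rose and 13 fell over the list alone, median -0.75, adjusted p = 2.97e-11). Bnip3 (log2 -1.38 ± 0.046) fell. Out of 14 NF-kB and inflammatory genes, 3 rose and 9 fell (median -0.84, adjusted p = 2e-06). Interleukin 1 alpha, Il1a, (log2 -1.76 ± 0.07) fell. Out of 13 fatty acid oxidation and PPAR targets, 0 rose and 6 fell (median -0.12, adjusted p = 0.0129, estimated 0.172). Ehhadh (log2 -2.11 ± 0.11) fell. Out of 19 nuclear-encoded OXPHOS genes, 12 rose and 0 fell (13 rose and 0 fell over the list alone, median 0.3, adjusted p = 0.0408, estimated 0.678). Ndufa4 (log2 1.95 ± 0.16) rose. The ribosomal protein share of counts was 7.75%, 4.46% and 5.50% in the 3 passage 15 libraries. With length and GC offsets the OXPHOS list's adjusted p was 0.076.

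Here 7761 genes were called, 3735 higher and 4026 lower at passage 15, and 1653 by 2-fold or more. With only the groups compared in the fit the count was 3631. Calls lost with DESeq2 (adjusted p) were Synpr (0.181) and Tex19.2 (0.163). Calls lost with only the groups compared in the fit (adjusted p) were Xbp1 (0.116) and Ptgs2 (0.0551).

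In the knockout organoids pit cell genes were mostly higher at passage 10 than at passage 5. Gpx4 did not pass (95.4 ± 6.5 against 99.5 ± 1.7 CPM, log2 -0.06, adjusted p = 0.909), and Bhlha15 fell (5.8 ± 0.32 against 10.2 ± 0.58 CPM, log2 -0.81 ± 0.14, adjusted p = 0.000369). Of 8 pit cell genes, 5 rose and 2 fell (6 rose and 2 fell over the list alone, median 0.77, adjusted p = 5.63e-12), with Muc5ac (188 ± 12 against 57 ± 1.9 CPM, log2 1.72 ± 0.11, adjusted p = 6.76e-10), Gkn2 (553 ± 23 against 247 ± 7.7 CPM, log2 1.16), Psca (103 ± 5.4 against 48 ± 0.88 CPM, log2 1.1) and Gkn1 (349 ± 17 against 159 ± 2.4 CPM, log2 1.14). Highest were the aryl hydrocarbon receptor targets Cyp1a1 (1.55 ± 0.74 CPM against 0 counts, at least 28.1-fold) and Cyp1b1 (log2 6.14 ± 0.45), with Rps6ka6 (2.82 ± 0.33 against 0.0175 ± 0.03 CPM, ratio 152, interval 26.7 to 6030, 1 count), Runx3 (1.41 ± 0.31 against 0.0359 ± 0.031 CPM, ratio 38.2, interval 10.2 to 322, 2 counts), Msx1 (0.681 ± 0.26 against 0.0185 ± 0.032 CPM, ratio 35.9, interval 6 to 1460, 1 count) and Hs6st2 (log2 4.07 ± 0.47). The lowest were Pdpn (log2 -6.22 ± 0.44), Tmem154 (0.0183 ± 0.032 against 1.18 ± 0.065 CPM, ratio 56.1, interval 9.71 to 2250, 1 count), F5 (0.0665 ± 0.064 against 2.85 ± 0.43 CPM, ratio 45.1, interval 15.2 to 221, 3 counts), the mucin Muc5b (log2 -3.99 ± 0.14), Map10 (0.0183 ± 0.032 against 0.389 ± 0.073 CPM, ratio 18.7, interval 3.01 to 773, 1 count) and Galnt5 (log2 -3.78 ± 0.57). Called genes had an adjusted p up to 0.00357.

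Of 4 chief cell genes, 1 rose and 3 fell (median -0.23). Pgc (log2 0.85 ± 0.12) rose, and Xbp1 (log2 -0.25 ± 0.048) and Rab3d (log2 -0.21 ± 0.053) fell. Of 9 mucous neck and SPEM genes, 1 rose and 3 fell (1 rose and 4 fell over the list alone, median -0.06, adjusted p = 5.12e-08). Dmbt1 (log2 -1.56 ± 0.075) and Tff2 (log2 -1.83 ± 0.17) fell, and Aqp5 (log2 1.02 ± 0.13) rose. Of 6 parietal cell genes, 1 rose and 3 fell (median -0.85, adjusted p = 0.0213, estimated 0.0555). Clic6 (log2 -1.47 ± 0.26) fell, and Slc9a4 (log2 0.34 ± 0.066) rose. Of 10 stem and isthmus genes, 2 rose and 0 fell (3 rose and 0 fell over the list alone, median -0.04, mean 0.19 but camera upward, adjusted p = 0.0685). Tnfrsf19 (log2 1.74 ± 0.19) and Bmi1 (log2 0.32 ± 0.062) rose. Of 8 intestinal genes, 2 rose and 2 fell (2 rose and 4 fell over the list alone, median -0.48, adjusted p = 1.97e-07). Olfm4 (log2 -2.34 ± 0.075) fell, and Lyz1 (log2 1.34 ± 0.23) rose. Also counted were squamous genes (1 rose and 0 fell of 4, median 0.19). For passage 10 against passage 5, Gpx4 knockout organoids, the parietal list's adjusted p was 0.282 without wild-type passage 15 in the fit.

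Of 17 ferroptosis defence genes, 2 rose and 0 fell (4 rose and 1 fell over the list alone, median 0, adjusted p = 0.131). Mboat2 (log2 0.74 ± 0.089) and Mboat1 (log2 0.22 ± 0.041) rose. Of 14 ferroptosis drivers and markers, 3 rose and 0 fell (3 rose and 2 fell over the list alone, median 0.09, adjusted p = 0.319). Tfrc (log2 0.44 ± 0.1) and Chac1 (log2 0.49 ± 0.15) rose. Of 22 NRF2 targets, 3 rose and 0 fell (3 rose and 1 fell over the list alone, median -0.02, mean 0.01 but camera upward, adjusted p = 0.646). Me1 (log2 0.3 ± 0.047) and Nqo1 (log2 0.41 ± 0.1) rose.

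Of 13 immediate early and heat shock genes, 1 rose and 7 fell (median -0.26, adjusted p = 1.17e-08). Hspa1b (log2 -0.6 ± 0.071) fell. Of 20 proliferation genes, 5 rose and 0 fell (11 rose and 0 fell over the list alone, median 0.15, adjusted p = 0.000178). Ccnb1 (log2 0.31 ± 0.057) rose. Of 17 p53 targets, 0 rose and 3 fell (0 rose and 7 fell over the list alone, median -0.14, adjusted p = 0.000623). The cell cycle inhibitor Cdkn1a (log2 -0.41 ± 0.055) fell. Of 14 NF-kB and inflammatory genes, 2 rose and 5 fell (2 rose and 6 fell over the list alone, median -0.16, adjusted p = 0.00125, estimated 0.0555). Icam1 (log2 -0.85 ± 0.056) fell. Of 11 mitochondrially encoded mRNAs, 0 rose and 3 fell (0 rose and 4 fell over the list alone, median -0.19, adjusted p = 0.00125, estimated 0.069). mt-Cytb (log2 -0.28 ± 0.049) fell.

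Of the genes tested, 1150 were called, 588 higher and 562 lower at passage 10, and 261 by 2-fold or more. The count was 3059 with only the groups compared in the fit and 3330 without wild-type passage 15. Fits without 1 library of these groups lost the calls (adjusted p) of Rab3d (3 of 6 fits, up to 0.0956), Chac1 (5 of 6 fits, up to 0.225) and Nqo1 (3 of 6 fits, up to 0.0836).

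Knockout organoids at passage 15 had higher pit cell genes than at passage 5. Gpx4 was not called (85.9 ± 2.5 against 99.5 ± 1.7 CPM, log2 -0.21, adjusted p = 0.391), although it was without wild-type passage 15 in the fit (adjusted p = 2.85e-06). Bhlha15 was not called (11.1 ± 0.11 against 10.2 ± 0.58 CPM, log2 0.13, adjusted p = 0.614). Among 8 pit cell genes, 8 rose and 0 fell (median 1.15, adjusted p = 1.55e-42), with Muc5ac (654 ± 3.1 against 57 ± 1.9 CPM, log2 3.52 ± 0.11, adjusted p = 4.35e-15), Gkn2 (1270 ± 19 against 247 ± 7.7 CPM, log2 2.36), Gkn1 (780 ± 5.9 against 159 ± 2.4 CPM, log2 2.29) and Psca (109 ± 5.7 against 48 ± 0.88 CPM, log2 1.18). The highest genes were Rps6ka6 (1.11 ± 0.17 against 0.0175 ± 0.03 CPM, ratio 59.9, interval 10.3 to 2410, 1 count), Msx1 (0.86 ± 0.27 against 0.0185 ± 0.032 CPM, ratio 46.2, interval 7.87 to 1870, 1 count), Ildr2 (0.843 ± 0.11 against 0.0201 ± 0.035 CPM, ratio 45.2, interval 7.69 to 1830, 1 count), Runx3 (0.703 ± 0.4 against 0.0359 ± 0.031 CPM, ratio 18.9, interval 4.87 to 162, 2 counts), Sema3a (0.883 ± 0.14 against 0.0554 ± 0.096 CPM, ratio 15.8, interval 5.06 to 79.3, 3 counts) and the mucus regulator Clca1 (log2 3.54 ± 0.056). The lowest were F5 (0 counts against 2.85 ± 0.43 CPM, at least 48.2-fold), Kctd12b (0 counts against 2.17 ± 0.13 CPM, at least 37.1-fold), Cfap47 (0 counts against 1.78 ± 0.37 CPM, at least 30.5-fold), the secreted glycoprotein Olfm4 (log2 -7.67 ± 0.12), Serpina10 (0 counts against 1.2 ± 0.22 CPM, at least 20.3-fold) and Nup62cl (0 counts against 1.15 ± 0.25 CPM, at least 19.7-fold). Adjusted p of the called genes was at most 0.000706.

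Among 4 chief cell genes, 2 rose and 0 fell (median 0.2). Rab3d (log2 0.27 ± 0.053) and Pgc (log2 0.36 ± 0.12) rose, and Xbp1 (log2 -0.01 ± 0.048, adjusted p = 0.935) did not pass. Among 9 mucous neck and SPEM genes, 2 rose and 3 fell (3 rose and 3 fell over the list alone, median -0.13, adjusted p = 0.403). Dmbt1 (log2 -1.03 ± 0.073) fell, and Sox9 (log2 0.59 ± 0.054) rose. Among 6 parietal cell genes, 2 rose and 2 fell (median -0.48, adjusted p = 0.291). Ckb (log2 -2.26 ± 0.34) and Clic6 (log2 -1.52 ± 0.25) fell, and Slc9a4 (log2 0.3 ± 0.066) rose. Among 10 stem and isthmus genes, 3 rose and 1 fell (3 rose and 3 fell over the list alone, median -0.01, mean 0.22 but camera upward, adjusted p = 0.0765). Tnfrsf19 (log2 2.03 ± 0.18) and Bmi1 (log2 0.52 ± 0.062) rose, and Axin2 (log2 -0.44 ± 0.14) fell. Among 8 intestinal genes, 0 rose and 3 fell (1 rose and 3 fell over the list alone, median -0.32, adjusted p = 2.84e-16). Vil1 (log2 -0.33 ± 0.042) fell. Also counted were squamous genes (0 rose and 1 fell of 4, 0 rose and 4 fell over the list alone, median -0.9).

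Among 17 ferroptosis defence genes, 1 rose and 7 fell (median -0.16, adjusted p = 0.0765). Nfe2l2 (log2 -0.28 ± 0.041) fell, and Mboat2 (log2 0.47 ± 0.09) rose. Among 14 ferroptosis drivers and markers, 1 rose and 3 fell (1 rose and 4 fell over the list alone, median -0.06, adjusted p = 0.128). Hmox1 (log2 -0.63 ± 0.067) and Ptgs2 (log2 -1.6 ± 0.18) fell, and Lpcat3 (log2 0.28 ± 0.05) rose. Among 22 NRF2 targets, 4 rose and 10 fell (4 rose and 11 fell over the list alone, median -0.15, adjusted p = 0.0446, estimated 0.204). Srxn1 (log2 -0.49 ± 0.055) fell, and Cbr1 (log2 0.56 ± 0.1) rose.

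Among 13 YAP targets and regenerative genes, 0 rose and 12 fell (median -0.56, adjusted p = 5.14e-33). Ly6a (log2 -2.23 ± 0.085) fell. Among 13 immediate early and heat shock genes, 0 rose and 9 fell (0 rose and 11 fell over the list alone, median -0.45, adjusted p = 8.73e-20). Dusp1 (log2 -1.51 ± 0.072) fell. Among 17 p53 targets, 0 rose and 10 fell (0 rose and 12 fell over the list alone, median -0.31, adjusted p = 3.26e-14). Plk2 (log2 -1.33 ± 0.045) fell. Among 14 NF-kB and inflammatory genes, 2 rose and 6 fell (2 rose and 7 fell over the list alone, median -0.14, adjusted p = 0.000322). The chemokine Cxcl2 (log2 -1.12 ± 0.074) fell. Among 15 integrated stress response genes, 2 rose and 4 fell (2 rose and 6 fell over the list alone, median -0.12, adjusted p = 0.000962, estimated 0.149). Atf3 (log2 -2.56 ± 0.068) fell. Among 10 Wnt targets, 0 rose and 4 fell (0 rose and 8 fell over the list alone, median -0.41, adjusted p = 0.00726). Myc (log2 -0.4 ± 0.055) fell.

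Between passages 5 and 15 of the knockout, 1960 genes were called, 872 higher and 1088 lower at passage 15, and 535 by 2-fold or more. The count was 4606 with only the groups compared in the fit and 4492 without wild-type passage 15. Fits without 1 library of these groups lost the calls (adjusted p) of Pgc (4 of 6 fits, up to 0.336) and Axin2 (5 of 6 fits, up to 0.148).

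The change from passage 5 to 15 differed between knockout and wild-type organoids, and the values of this interaction are log2 differences ± SE, where rose means a more positive change in the knockout. Gpx4 did not pass (-0.34 ± 0.19, adjusted p = 0.168), and Bhlha15 rose (1.19 ± 0.21, adjusted p = 0.000157). Pit cell genes numbered 8, of which 8 rose and 0 fell (median 3.36, adjusted p = 2.21e-60), with Muc5ac (6.03 ± 0.16), Gkn2 (4.81 ± 0.13), Mucl3 (3.56 ± 0.076) and Ctse (1.96 ± 0.067). The condition that libraries do not overlap could not be applied to 4 groups. The highest values were of Tfap2a (log2 11.72 ± 1.7), Irx5 (log2 10.06 ± 0.4), Lipo3 (log2 9.5 ± 0.38), Capn11 (log2 9.08 ± 2.7), Actn2 (log2 8.69 ± 1.3) and Zcchc3 (log2 8.58 ± 0.95). The lowest were Ereg (log2 -11.03 ± 0.44), Pdpn (log2 -9.56 ± 0.58), Cdx2 (log2 -8.41 ± 0.86), Il5ra (log2 -7.03 ± 0.92), Cdhr5 (log2 -6.95 ± 0.65) and Ifitm3 (log2 -6.87 ± 0.6). Fitted values of genes at 0 counts in a group depend on the prior count and are no bounds. Called genes had an adjusted p up to 0.012.

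Out of 20 proliferation genes, 0 rose and 16 fell (0 rose and 19 fell over the list alone, median -0.61, adjusted p = 1.87e-08). Mcm5 (log2 -0.77 ± 0.067) and Rrm2 (log2 -0.8 ± 0.074) fell. Out of 4 chief cell genes, 4 rose and 0 fell (median 1.09). Pgc (log2 2.33 ± 0.17), Rab3d (log2 1.00 ± 0.075) and Xbp1 (log2 0.24 ± 0.068) rose. Out of 9 mucous neck and SPEM genes, 4 rose and 1 fell (median -0.08, mean 0.72 but camera upward, adjusted p = 1.77e-05). Dmbt1 (log2 3.75 ± 0.14) and Gkn3 (log2 2.03 ± 0.11) rose. Out of 6 parietal cell genes, 2 rose and 1 fell (median 0.01, adjusted p = 0.14). Slc9a4 (log2 1.76 ± 0.094) and Kcnq1 (log2 0.56 ± 0.1) rose, and Atp4a (log2 -1.33 ± 0.32) fell. Out of 10 stem and isthmus genes, 2 rose and 1 fell (3 rose and 3 fell over the list alone, median 0.06, adjusted p = 0.983). Runx1 (log2 0.57 ± 0.1) rose, and Stmn1 (log2 -0.64 ± 0.14) fell. Out of 8 intestinal genes, 1 rose and 5 fell (median -3.14, adjusted p = 0.0931). Out of 4 squamous genes, 0 rose and 4 fell (median -1.71).

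Out of 17 ferroptosis defence genes, 4 rose and 5 fell (4 rose and 6 fell over the list alone, median -0.18, mean 0.01 but camera downward, adjusted p = 0.955). Mboat2 (log2 1.39 ± 0.14) rose, and Gss (log2 -0.56 ± 0.11) fell. Out of 14 ferroptosis drivers and markers, 5 rose and 2 fell (median 0.09, adjusted p = 0.832). Sat1 (log2 1.01 ± 0.077) rose, and Ptgs2 (log2 -2.4 ± 0.25) fell. Out of 22 NRF2 targets, 5 rose and 7 fell (median -0.11, mean 0.01 but camera downward, adjusted p = 0.983). Ugdh (log2 0.72 ± 0.06) and Me1 (log2 0.8 ± 0.067) rose, and Hmox1 (log2 -0.73 ± 0.092) fell.

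Out of 13 YAP targets and regenerative genes, 2 rose and 11 fell (median -0.62, adjusted p = 9.02e-11). Out of 17 p53 targets, 1 rose and 14 fell (median -0.54, adjusted p = 1.87e-06). Plk2 (log2 -1.65 ± 0.063) fell. Out of 16 hypoxia and glycolysis genes, 10 rose and 0 fell (median 0.48, adjusted p = 7.92e-07). Bnip3 (log2 1.28 ± 0.063) rose. Out of 13 immediate early and heat shock genes, 1 rose and 7 fell (median -0.37, adjusted p = 0.00335, estimated 0.0929). Dusp1 (log2 -1.46 ± 0.1) fell. Out of 14 NF-kB and inflammatory genes, 9 rose and 3 fell (median 0.51, adjusted p = 0.00501, estimated 0.0937). Nfkbia (log2 1.12 ± 0.072) rose.

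The interaction called 5794 genes, 2984 higher and 2810 lower, and 1611 by 2-fold or more on the same scale. It rests on the wild-type passage 15 libraries, whose spread is given above. Fits without 1 library of these groups lost the calls (adjusted p) of Capn11 (1 of 12 fits, 1 without knockout passage 15 replicate 2). The call of Xbp1 was lost (adjusted p) with library totals alone (0.0821), no low-count filter (0.167) and only the groups compared in the fit (0.101). Calls lost with only replicate 2 of wild-type passage 15 (adjusted p) were Atp4a (0.051).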

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

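The number of splits was set before the result was seen, and all other tests of explanations here were chosen after it. The interaction of genotype with passage 15 against 5 called 5794 genes. Bhlha15 differed by a log2 of 1.19. The highest values were 11.72 for Tfap2a, 10.06 for Irx5, 9.5 for Lipo3, 9.08 for Capn11, 8.69 for Actn2 and 8.58 for Zcchc3. The lowest were -11.03 for Ereg, -9.56 for Pdpn, -8.41 for Cdx2, -7.03 for Il5ra, -6.95 for Cdhr5 and -6.87 for Ifitm3. Pit cell genes differed by 3.56 for Mucl3, 6.03 for Muc5ac, 4.81 for Gkn2 and 1.96 for Ctse. Values of genes at 0 counts in a group are no bounds.

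Of 100 splits of the 12 libraries, 1, the real one, called as many genes as 5794, and the highest other called 3220. That split keeps the true passage 15 grouping, and the second highest called 3151, which points to a structure of the samples. In each of the other 8 comparisons there were 10 splits, too few for a share under 0.05, and 1 split, the real one, called as many genes. The highest other called 1 gene for wild-type passage 15 against 5 (real 7761). It called 0 for Mist1+ against Mist1- (5290), for knockout against wild type at passages 5 (4547), 10 (5204) and 15 (7396), for wild-type passage 10 against 5 (738), and for knockout passages 10 (1150) and 15 (1960) against 5. Other splits mix unlike groups, which widens the spread, so their lower counts show only that libraries of a group resemble each other.

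The interaction rests on wild-type passage 15, whose libraries stood apart from wild-type passages 5 and 10. A gene length or RNA quality bias as the whole cause is argued against by 88.9% (1469 of 1653) of the genes at 2-fold or more staying so with length and GC offsets. Taken alone, the first test pointed to libraries swapped with knockout libraries: over 1051 genes the signed median was 0.99 (quartiles 0.28 and 1.99), against 0.98 (0.32 and 2) in knockout passage 15. A second test, chosen after that one, took 134 genes at 4-fold or more at passages 5 and 10, and counted a gene as near a level when less than 25% of the log2 distance from it, or beyond it. In wild-type passage 15, 53 lay near the wild-type and 58 near the knockout level, and in knockout passage 15, 6 and 105. This argues against libraries swapped with, or drawn from, these knockout cultures. In Mist1- libraries they were 49 and 64, so these genes are not specific to knockout cultures. For a swap with Mist1- libraries the first test decided nothing, with a median of 0.58 (quartiles -0.14 and 1.48) against 1.43 (1.01 and 2.24) over 1337 genes. Of 350 genes, 127 lay near the wild-type and 99 near the Mist1- level, which argues against libraries swapped with or drawn from Mist1- cultures, although no Mist1- library of a later passage was there to compare.

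A minor share of other cells is argued against by 21 genes at 10 CPM or more in each wild-type passage 5 and 10 library and at an eighth or less in each passage 15 library. The transcription factor Gata6 was at least 44.6 CPM and at most 1.23 CPM. A steady change over passages is argued against by a median of 7.2% of the log2 change being present at passage 10 (quartiles -9.7 and 25.4), although both measures share the passage 5 libraries. Another culture or line, and a late change of these organoids, may both explain the pattern. They stay open, since 1 set of libraries stands for each passage.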

How the results depend on the processing

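The settings named above as added were chosen after seeing the data. The causes were not tested, except that the 2-fold threshold can only lower a count. Fits without wild-type passage 15 raised the counts below. Fits of it with only 1 other group lowered them, which goes with its wide spread. With only the groups compared the counts were 7035 (knockout against wild type, passage 5), 2735 (passage 15), 2827 (wild type, passage 10 against 5), 3631 (15 against 5), 3059 (knockout, 10 against 5) and 4606 (15 against 5). Without the wild-type passage 15 libraries they were 7095 (knockout against wild type, passage 5), 2766 (wild type, 10 against 5), 3330 (knockout, 10 against 5) and 4492 (15 against 5). Length and GC offsets gave 1164 for wild type, 10 against 5. With a 2-fold threshold they were 1337 (Mist1+ against Mist1-), 1004, 1051 and 1627 (knockout against wild type), 113 and 1653 (wild-type passages), 261 and 535 (knockout passages) and 1611 (interaction). Other settings kept the counts within 1.5 times.

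Leaving out 1 replicate gave 4506 to 4569 (Mist1+ against Mist1-), 3776 to 3828, 4333 to 4402 and 6323 to 9140 (knockout against wild type at passages 5, 10 and 15), 500 to 529 and 6821 to 9270 (wild-type passages), 818 to 882 and 1500 to 1523 (knockout passages) and 5099 to 7956 (interaction). The 3 highest values, 9140, 9270 and 7956, were without wild-type passage 15 replicate 2. With only that replicate the counts were 5548 (knockout against wild type), 6567 (wild type) and 6119 (interaction), and this lone sample is assumed to vary like the other groups, which its own group did not. With the replicate number as a block 5242, 4510, 5157, 7375, 706, 7731, 1102, 1888 and 5756 genes were called.

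Of 234 list tests 108 passed, 68 with an estimated correlation (40 lost), 184 by fry (1 lost, 77 gained), 101 with offsets (13 lost, 6 gained), 104 with a replicate block (4 lost) and 107 with median ratio scaling (1 lost). Of 156 tests 77 passed, and 87 without wild-type passage 15 (5 lost, 15 gained). Of 78 tests 31 passed, and 39 with only its replicate 2 (3 lost, 11 gained). Printed lists among the lost were, with the block, ferroptosis defence in knockout against wild type at passage 15 (also with median ratio scaling), unfolded protein response in Mist1+ against Mist1-, mucous neck in knockout against wild type at passage 10 (also with offsets) and parietal in wild-type passage 15 against 5. The others were OXPHOS in that comparison (only replicate 2 or offsets), and interferon in Mist1+ against Mist1- and parietal in knockout passage 10 against 5 (without wild-type passage 15, the latter also with offsets). Library totals alone moved the share of higher calls, to 43.4% from 53.7% for Mist1+ against Mist1-, 60.9% from 43.3% and 60.4% from 46.3% for knockout against wild type at passages 5 and 10, 60.4% from 48.1% for wild-type passage 15 against 5 and 38% from 51.5% for the interaction. Limma at a pseudocount of 1 gave 41.9%, 62.6%, 61.3%, 61.2% and 37.4% for these.

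Named genes that reversed follow. Xbp1 in wild type, 10 against 5, was 0.01 with library totals alone, no low-count filter and limma at both pseudocounts, 0 with a mean FPKM of at least 1 and in 3 leave-one-out fits (range -0.01 to 0), and 0.02 with quantile scaling and offsets. Leave-one-out gave Xbp1 values of -0.01 to 0.01 in Mist1+ against Mist1-, reversed in 2 fits. In knockout passage 15 against 5 it was 0.02 with offsets and -0.02 to 0 in leave-one-out fits. For mt-Nd2 in knockout against wild type at passage 10 quantile scaling gave 0.43. Clic6 in the interaction was -0.15 with limma and -0.35 with quantile scaling. Gpx4 in wild type, 15 against 5, was -0.32 with only replicate 2, -0.1 with offsets and -0.16 to 0.31 in leave-one-out fits, lowest without replicate 1. It was 0.1 in the interaction with only replicate 2. Without wild-type passage 15 in the fit Gpx4 was also called in Mist1+ against Mist1-, wild-type passage 10 against 5 and knockout passage 15 against 5. Leave-one-out ended a named gene's call 141 times, and depth limits the genes given as bounds or ratios. The planned diet comparison was not run.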

Other observations

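All tests here were chosen after the data were seen. Of 339 KEGG pathways, camera placed 20 past the threshold in Mist1+ against Mist1- organoids, and 23, 45 and 15 in knockout against wild type at passages 5, 10 and 15. With an estimated correlation these were 3, 3, 15 and 4. Linoleic acid metabolism (15 genes tested) had the smallest p in Mist1+ against Mist1- organoids, where 10 rose and 2 fell (adjusted p = 2.58e-06, estimated 0.0473). In knockout against wild type 1 rose and 8 fell at passage 5 (0.000308, estimated 0.0612), 1 rose and 10 fell at passage 10 (1.03e-08, estimated 0.00831), and 6 rose and 1 fell at passage 15 (0.0279, estimated 0.35).

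Knockout and wild-type organoids differed by 4-fold or more in 314 genes at passage 10. Variation between wild-type organoid cultures was tested on the Mist1- and Mist1+ libraries, in which 123 of these genes also differed by 4-fold or more. Expression-matched genes gave a median of 19 and at most 35 over 10000 draws. Such variation, also of the Mist1+ organoids in both differences, may account for part of these. The knockout itself and the Mist1 sort stay open, since each group is 1 set of libraries.

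Gpx4 counts were modestly lower in the libraries labelled knockout. Outgrowth of cells with intact Gpx4 over passages stays open. The log2 difference between knockout passages 15 and 5 was -0.21 (SE 0.14, upper limit 0.05), a fall that was called without wild-type passage 15 in the fit (adjusted p = 2.85e-06) and goes against outgrowth, but the wild type may have changed too. Relative to it the change was -0.34, and 0.1 with only replicate 2 of wild-type passage 15. Transcript left after exons are deleted may also explain the level, and counts per gene cannot show it.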
